A study of Rattus norvegicus with 354 samples.

How the data were processed

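The study measured gene expression in brain tissue of female Sprague-Dawley rats after 1 oral gavage of RDX, a nitramine explosive that causes seizures, or of vehicle. The labels give 4 doses (1.2, 12, 24 and 47 mg/kg) and a control, called 0 mg/kg here, at 6 times after dosing (24 hr, 48 hr, 7, 14, 28 and 90 days). There were 30 groups of 3 animals, 90 animals in all. The 354 samples are the single channels of 177 arrays, each of which carried RNA of 1 animal in Cy3 and RNA of another in Alexa 647. The animals of 1 time were joined in an interwoven loop, per the labels' protocols. Each animal was on 3 to 5 arrays (median 4), and 80 animals were on 2 arrays in each dye. These counts include 1 array that was left out of the main results (below), which was 1 of the 3 arrays of 24 hr control replicate 3. The animal was the replicate in every test, and arrays of the same animal were never counted as replicates.

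The deposited array files hold spot intensity as scanned, with the local background and a net intensity for both channels, per the file headers. For 176 arrays both deposited files were identical, so each array was read once. The deposited sample tables hold 1 normalized log2 value per probe, per the file headers, and the submitters' processing notes name limma without a version. These log2 values ranged from -10.24 to 17.88, the sample medians ranged from 9.46 to 11.8, and the median correlation across probes with the log2 signal of the sample's own channel was 0.992. They were used in an alternative setting, not in the main results. On 42 arrays the signals were trimmed means, on the others plain means. One array had 7812 of the 8064 spots, and 271 spots per array were control spots that were left out. The arrays held 7616 probe identifiers.

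The channel of each animal was taken from the order of the animals in the array names, the first being Cy3. The deposited values followed this order in both channels of 176 arrays. In 1 array of 24 hr, which set 47 mg/kg replicate 1 against control replicate 3, they followed the opposite order. The other arrays of the loop predicted its log2 ratios with r = 0.288 across probes when the 47 mg/kg animal was read as Cy3, and with r = -0.288 otherwise. For the other 28 arrays of 24 hr this r had a median of 0.092 and ranged from -0.153 to 0.664. The loop thus went better with the order in the array name, without settling it. This array was left out of the main results before any test, although the plan had been to use all arrays, and both readings were run as alternatives.

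Signals were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50) and normalized within each array by loess. A linear fit per probe and time over all arrays of that time, with a dye term, gave 1 relative log2 value per animal. A probe was left out at a time when its foreground exceeded the local background in under 0.5 of the channels, which removed 18 probes at 7 days, 1 at 14 days and 0 at the other times. Tables were handled with data.table (version 1.17.8) and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

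Each dose was compared with the control of the same time in a limma fit over the 15 animals of that time, with 5 groups of 3. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A dose trend was tested over the same 15 animals as a slope on log2(dose + 1). An F-test of limma over all 90 animals asked whether the 47 mg/kg effect differed between the 6 times. No array joined animals of different times, so values are relative within a time and control animals were not compared across times. By the slide codes in the sample titles, 1 array of 14 days belonged to the slide batch of 90 days, and 24 and 48 hr had codes nearly alike without a shared slide number, so both may come from 1 batch. The other times each had a batch of their own. Of 26 gene lists fixed before the data were examined, 25 had at least 5 measured genes, and the choroid plexus list, with 4, was not tested. They were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation, and fry, and p was adjusted over all 600 tests of a list in a comparison. The list tests of the 24 hr dose trend were a separate family, adjusted over 25 lists alone. A gene with several probes was represented in the lists by its brightest probe.

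Probes were named through a RefSeq gene table of the rat assembly GRCr8, used for names only, by accession (1893 probes), by a symbol in the array's description (250) or by a synonym there (392). This gave 2482 genes, 48 of them with several probes, and 5081 probes had no symbol and are called by their description. For 6 probes the matched name contradicted the description and was set aside. Genes were named by a rule fixed before the data were examined. It took, for each dose, up to 10 passing probes with a symbol each way whose 3 dosed animals all lay on 1 side of the 3 controls, and up to 4 passing members per list. With fewer than 5 passing probes it took the 5 with the smallest p, and at 47 mg/kg also 18 fixed genes, of which the array held 13. For trends it took up to 5 each way by smallest p. Another 3 genes that it took are not reported here. The text does not name every gene that the rule took, and leaves out 4 of the fixed genes on the array (Gabrb2, Grin1, Gria1 and Hmox1), of which none passed at 47 mg/kg. The members of called lists, further trending genes with a symbol, the probes named under differences between times and the trend test over gene lists were chosen after their values were seen.

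The precision was limited by the number of arrays and by their signal. The median foreground was 3.58 times the background in Cy3 and 1.69 times in Alexa 647 at 24 hr, 3.8 and 2.03 times at 48 hr, 1.33 and 1.27 times at 7 days, 3.22 and 2.6 times at 14 days, 2.96 and 2.1 times at 28 days, and 3.27 and 1.5 times at 90 days. The spread between arrays after the loop fit was 0.23 to 0.356 log2 (SD). The spread of the fitted animal values within a group was 0.132 to 0.203, which includes array error and is not the spread between rats alone. When each of 176 arrays was predicted from the other arrays of its loop, the median r across probes was 0.041 to 0.092 per time, and it was below 0 for 49 arrays.

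The procedure was tested on simulated data with 50 probes changed at each size. For 47 mg/kg against control at 24 hr (7616 probes) it recovered 28% of changes of 0.5 log2, 86% of changes of 1 and 100% of changes of 1.5, with 3 false calls. For the dose trend at 24 hr (7616 probes) it recovered 44% of rises of 0.5 log2 and 98% of rises of 1, with 18 false calls. For effects differing between times (7597 probes) it recovered 18% at 0.5 and 82% at 1, with 6 false calls. With no simulated effect each test made 0 calls. The simulated noise was independent between probes, and for effects differing between times it was drawn per animal without arrays. Error shared across probes was thus not simulated, so these false calls may understate those in the real data.

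Alternatives fixed before the data were examined were no background correction, median centring without loess, separate channels after quantile normalization, the submitters' values, no filter, no repeat arrays (11 arrays left out), no dye term, the replicate number as a block, dose as its rank, 1 fit over 90 animals, and leaving out each animal in turn. Another 8 were chosen after seeing the data: array quality weights, print-tip loess, both readings of the array left out, the 90 day data without the 2 arrays with the widest log2 ratios, a stricter filter (foreground 1.5 times background), the 14 day data without the array of the other slide batch, and the submitters' values centred on each sample's median. The replicate numbers showed no clear pairing of animals across doses: the median correlation of animals with the same number was -0.0201 to 0.0833 per time. For animals with other numbers it was -0.0477 to 0.0304. Per time, 6 to 9 of 15 animals correlated best with their own number, so a weak pairing is not excluded.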

Results

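Brain gene expression was measured in 90 female rats on 177 two-colour arrays (Cy3 and an Alexa dye) after a single oral dose of RDX or vehicle. Each of 6 times from 24 hr to 90 days had a control group and groups at 1.2, 12, 24 and 47 mg/kg, with n = 3 animals per group. The study asked which genes change in the brain after RDX and at which dose and time. Values are log2 differences between animals, with the standard error (SE) of limma's fit, and tests are two-sided with Benjamini-Hochberg adjusted p. Median foreground over background in Cy3 ranged from 1.33 at 7 days to 3.8 at 48 hr, so the signal stood out least from the background at 7 days.

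At 24 hr, single genes of synaptic vesicles, astrocytes and protein folding were higher with rising dose. Vamp2, the vesicle protein synaptobrevin 2, rose by 1.05 log2 from 0 to 47 mg/kg along the fitted slope (2.07-fold, limma adjusted p = 0.0185, 15 animals). Glul, the glutamine synthetase of astrocytes, rose by 1.02 log2 (2.03-fold), and Gfap, the intermediate filament of astrocytes, by 0.99 (1.99-fold). Cck, a neuropeptide, rose by 0.92, and the endoplasmic reticulum chaperones Pdia3, Hsp90b1 and Hspa5 rose by 0.88, 0.85 and 0.50. The smallest adjusted p (0.00853) belonged to probes described as glia-derived nexin, a protease inhibitor, and amyloidogenic glycoprotein, the rat cognate of the amyloid precursor protein, with rises of 0.90 and 1.15. Cartpt and Agrp, neuropeptides of feeding circuits, fell by 0.80 and 0.51, and the calcium pump Atp2c2 fell by 0.53.

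The dose trend at 24 hr covered 392 of 7616 probes in limma, 240 rising and 152 falling, with a median size of 0.504 log2 from 0 to 47 mg/kg (1894 probes at unadjusted p under 0.05). Of these, 147 had a gene symbol. By dose, Vamp2 was higher than control by 0.53, 0.89, 1.06 and 1.12 at 1.2, 12, 24 and 47 mg/kg, and Gfap by 0.07, 0.16, 0.57 and 1.19. The count fell to 5, 2 and 9 without control replicate 1, control replicate 3 or 47 mg/kg replicate 2, to between 123 and 259 without 24 mg/kg replicate 1 or 2, 1.2 mg/kg replicate 3 or 12 mg/kg replicate 1, and rose to 697 without control replicate 2. It was 0 in limma from separate channels and from the submitters' values (622 and 855 probes at unadjusted p under 0.05), and 165 or 3 with the left-out array read as 47 mg/kg in Cy3 or in the Alexa dye.

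Of the gene lists at 24 hr, 6 of 23 measured members of the synaptic vesicle list rose with dose (limma adjusted p under 0.05), among them Vamp2, Nsf, Atp6v0c and Rab3a, which act in vesicle fusion and filling. The list passed camera (adjusted p = 0.000476, but 0.243 with an estimated correlation), with 9 members passing when adjusted over the list alone. With an estimated correlation no list kept its call. The heat shock and protein folding list (5 of 18 rose, 9 adjusted over the list alone, camera adjusted p = 0.00373, 0.39 with an estimated correlation) and the astrocyte markers (4 of 14 rose, Glul, Atp1b2, Cpe and Gfap, 5 adjusted over the list alone, adjusted p = 0.00604, estimated 0.318) passed as well. The proteasome list passed with 1 of 18 members rising, Psma6 (4 adjusted over the list alone, adjusted p = 0.00604, estimated 0.463), and the glycolysis list with 2 of 23 (5 adjusted over the list alone, adjusted p = 0.047, estimated 0.318). The glycolysis call held in only 13 of 31 alternative settings with the preset correlation, each animal left out included. The other lists passing here held in 26 to 30 of them. In the neuropeptide list 3 members rose (Cck, Cpe and Chgb) and 2 fell (Cartpt and Agrp) out of 31, with 9 adjusted over the list alone (camera adjusted p = 0.0315, estimated 0.578). The xenobiotic metabolism list went down (camera adjusted p = 0.00869, estimated 0.318): 4 of 39 members fell, among them the oxygenases Cyp2d3 by 0.44 and Fmo2 by 0.56 and the glucuronosyltransferase Ugt2b by 0.50, and 4 fell adjusted over the list alone. With fry, the synaptic vesicle (adjusted p = 0.00625), xenobiotic metabolism (0.0185) and glycolysis (0.023) lists passed. The astrocyte (0.0295) and heat shock (0.0397) lists passed fry too, while the proteasome (0.0802) and neuropeptide (0.174) lists did not. Over all probes the 24 hr slope was higher for brighter probes (Spearman rho = 0.164). The lists were not tested again with brightness taken out, so a part of brightness in their directions stays open. The other 18 lists did not pass camera, among them neuronal structure markers (adjusted p = 0.106, 0 of 21 members passing in limma, 0 adjusted over the list alone) and calcium and calmodulin signalling (adjusted p = 0.115), where Prkcb, Ppp3cb and Ppp3r1 rose by 0.70, 0.61 and 0.68 and Hpcal4 fell by 0.47.

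**Figure D1:**
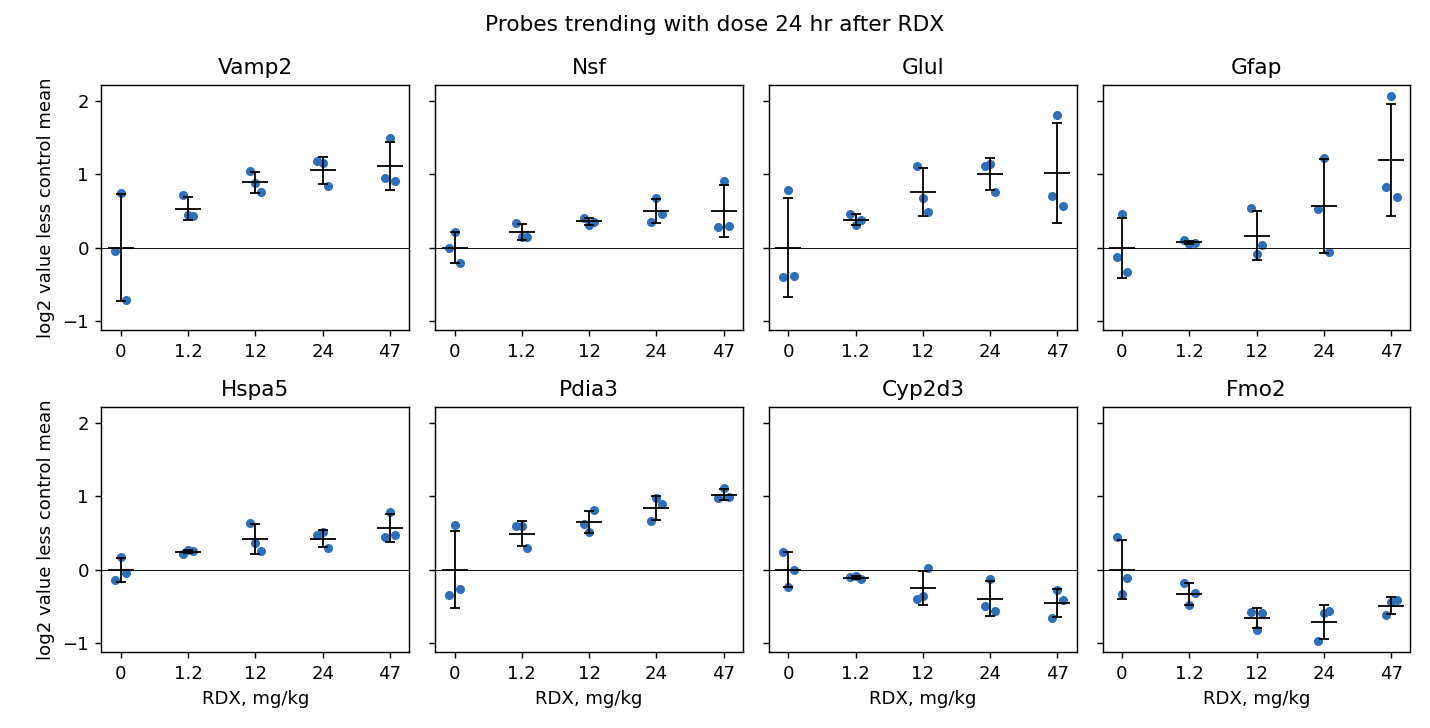
Log2 value relative to the control mean (vertical axis) against dose in mg/kg (horizontal axis) at 24 hr for 8 genes, with 1 point per animal and the mean and SD of 3 animals per dose. Vamp2, Nsf, Glul, Gfap, Hspa5 and Pdia3 lie higher with dose, and Cyp2d3 and Fmo2 lie lower.

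Single doses against control at 24 hr gave no passing probe. At 47 mg/kg, 0 of 7616 probes passed in limma (1246 at unadjusted p under 0.05, n = 3 per group). Hspb1, the small heat shock protein Hsp27, was 1.81 log2 higher (SE 0.56), Npy, an inhibitory neuropeptide, 1.31 higher (SE 0.31), and Gfap 1.19 higher (SE 0.33). Narp, a neuronal pentraxin induced by activity, had the smallest adjusted p (1.23 higher, SE 0.21, limma adjusted p = 0.119, n = 3), followed by Cck (1.09, SE 0.20) and Pdia3 (1.02, SE 0.19). The immediate early genes Arc (-0.65, SE 0.32) and Egr1 (-0.42, SE 0.20) were lower without passing, and Bdnf was 0.30 higher (SE 0.18). Values near 0 were seen for Junb (-0.05, SE 0.17), the microglial marker Aif1 (-0.02, SE 0.18), the GABA-synthesizing enzyme Gad1 (-0.04, SE 0.14) and the myelin gene Mbp (0.13, SE 0.12).

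At the lower doses of 24 hr the counts were also 0 in limma, with 260 probes at 1.2 mg/kg, 1027 at 12 mg/kg and 1311 at 24 mg/kg at unadjusted p under 0.05. At 24 mg/kg the smallest limma adjusted p was 0.0848 (n = 3), for probes of amyloidogenic glycoprotein (1.14 higher, SE 0.22), of microtubule-associated protein 1B (0.73, SE 0.14) and of Csnk2b, a casein kinase subunit (0.72, SE 0.14). At 12 mg/kg a Na,K-ATPase alpha subunit probe was 0.90 higher (SE 0.19) and at 1.2 mg/kg the vesicular glutamate transporter Slc17a6 was 0.71 higher (SE 0.18), neither passing. Without control replicate 2, 107, 370 and 380 probes passed at 12, 24 and 47 mg/kg, and 18 passed at 47 mg/kg without 47 mg/kg replicate 3. In 1 limma fit over all 90 animals, 45, 101 and 167 probes passed at these doses, among them at 47 mg/kg Narp, Npy, Pdia3, Hspb1, Cck and Gfap.

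Gene lists at 47 mg/kg and 24 hr were higher for heat shock and protein folding (median 0.25 log2, 15 of 18 members higher, camera adjusted p = 0.00303), proteasome (0.21, 15 of 18, adjusted p = 0.00845), synaptic vesicle (0.14, 18 of 23, adjusted p = 0.0148), neuropeptides (0.18, 22 of 31, adjusted p = 0.0148) and astrocyte markers (0.24, 11 of 14, adjusted p = 0.0235). None of these calls held with an estimated correlation (adjusted p = 0.858). Over all 7616 probes 0 of their members passed in limma (1246 probes at unadjusted p under 0.05), and adjusted over the list alone 6, 0, 4, 8 and 3 members passed. The neuropeptide members passing in the list alone were higher for Cck, Npy, Vgf (0.65, SE 0.17), Penk (0.83, SE 0.24), Sst (0.49, SE 0.16) and Cpe, and lower for Agrp (-0.49, SE 0.14) and Cartpt (-0.62, SE 0.19). At the lower doses of 24 hr the synaptic vesicle list was higher at 12 and 24 mg/kg (adjusted p = 0.0148 and 0.00883), the neuropeptide list at 1.2 and 12 mg/kg (0.00303 and 0.0148), heat shock and protein folding at 1.2 and 24 mg/kg (0.0358 and 0.046) and astrocyte markers at 24 mg/kg (0.0358). The xenobiotic metabolism list was lower at 24 mg/kg (median -0.18, 8 of 39 members higher, 0.0438). All of these had an adjusted p of 0.858 under an estimated correlation.

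At 48 hr, 0 of 7616 probes passed at 47 mg/kg in limma (504 at unadjusted p under 0.05, n = 3 per group). Gfap was 1.75 log2 higher (SE 0.40), Hspb1 1.56 higher (SE 0.39) and Npy 0.98 higher (SE 0.25). Trh, the thyrotropin-releasing hormone precursor, had the smallest limma adjusted p (1.40 higher, SE 0.27, adjusted p = 0.254, n = 3), followed by a probe described as Tclone15 (1.22, SE 0.24). A probe of metallothionein-1, a metal-binding protein, was 0.87 higher (SE 0.19). The microglia and immune cell list was higher in all 14 members (median 0.22, camera adjusted p = 0.00703, and adjusted p = 0.858 with an estimated correlation). Its member C1qb, a subunit of complement C1q, was 0.80 higher (SE 0.18) and was the 1 member to pass adjusted over the list alone, while 0 of 14 passed over all probes. Astrocyte markers (median 0.23, camera adjusted p = 0.0517) and blood and endothelial markers (0.22, adjusted p = 0.334) were higher by as much without passing. The difference between these lists was not tested.

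In 1 limma fit over all 90 animals, 11 probes passed at 47 mg/kg and 48 hr, 10 of them higher, among them Gfap, C1qb, Hspb1 and Sat1, the enzyme of polyamine breakdown (0.78). Without 47 mg/kg replicate 1, 7 probes passed. At 12 mg/kg 1 probe passed, described as an angiotensin/vasopressin receptor (0.98 higher, SE 0.14, limma adjusted p = 0.0254, n = 3, 1044 probes at unadjusted p under 0.05). The count was 2 without control replicate 1, 0 without control replicate 2 or any 1 of the 12 mg/kg animals, and also 0 without background correction, without the dye term, with print-tip loess, from separate channels and from the submitters' values. It was 161 in 1 fit over 90 animals and 36 with the replicate number as a block. No probe passed in limma at 1.2 or 24 mg/kg (0 each, 458 and 992 at unadjusted p under 0.05) or in the dose trend (0, 1027 at unadjusted p under 0.05), although the fit over 90 animals gave 3, 96 and 107. At 1.2 mg/kg the synaptic vesicle list was higher (median 0.22, 20 of 23 members, camera adjusted p = 0.00303, and 0.858 with an estimated correlation).

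At 7 days, 0 of 7598 probes passed at any dose or in the trend in limma (119, 456, 309 and 96 probes at 1.2, 12, 24 and 47 mg/kg and 345 in the trend at unadjusted p under 0.05). Gfap (0.07, SE 0.22), Npy (0.04, SE 0.18) and Hspb1 (-0.11, SE 0.19) were near the control value at 47 mg/kg. Lhb, a pituitary hormone subunit, was 0.92 higher (SE 0.29) without passing, and the 7 pituitary hormone genes had a median of 0.50 without the list passing camera. The synaptic vesicle list was lower at 12 mg/kg (median -0.14, 5 of 23 members higher, camera adjusted p = 0.0438, and 0.858 with an estimated correlation). In 1 fit over 90 animals 3 and 8 probes passed at 12 and 24 mg/kg and 14 in the trend, and without the repeat arrays 1 probe passed at 24 and at 47 mg/kg and 2 in the trend.

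At 14 days, 0 of 7615 probes passed at any dose or in the trend in limma (342, 544, 471 and 521 at 1.2, 12, 24 and 47 mg/kg and 804 in the trend at unadjusted p under 0.05). Stat3, a transcription factor of cytokine signalling, was 0.42 higher at 47 mg/kg (SE 0.08) and 0.37 higher at 12 mg/kg (SE 0.08), and Egr1 was 0.42 higher at 47 mg/kg (SE 0.11), none passing. Smad2, a mediator of TGF-beta signalling, was 0.55 higher at 12 mg/kg (SE 0.11) and 0.51 at 24 mg/kg (SE 0.11), also not passing. At 12 mg/kg the immediate early gene list (18 of 24 members higher) and the neuronal structure list (17 of 21) were higher (camera adjusted p = 0.0148 each, and 0.858 with an estimated correlation). From the submitters' values, whose samples differ in their median, 1452 and 874 probes passed at 12 and 24 mg/kg, all lower, and 0 with each sample centred (limma).

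At 28 days, 0 of 7616 probes passed at any dose or in the trend in limma (123, 276, 425 and 283 at 1.2, 12, 24 and 47 mg/kg and 899 in the trend at unadjusted p under 0.05). Cd93, a receptor of endothelial and myeloid cells, was 0.59 higher (SE 0.13) at 47 mg/kg. Ccn1, a secreted matrix protein, was 0.67, 0.61 and 0.59 below control in its log2 means at 12, 24 and 47 mg/kg (values of -0.67, -0.61 and -0.59, SE 0.15 each), without passing. The oxidative phosphorylation list was lower at 47 mg/kg (median -0.18, 4 of 14 members higher, 0 passing adjusted over the list alone, camera adjusted p = 0.0236, and 0.858 with an estimated correlation). In 1 fit over 90 animals 9 probes passed at 24 mg/kg and 297 in the trend.

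At 90 days, 2 of 7616 probes were lower at 47 mg/kg in limma (1122 at unadjusted p under 0.05), and both also fell with dose. Junb, an immediate early transcription factor, was -1.0 log2 against control (SE 0.16, n = 3, limma adjusted p = 0.0469), with values of -0.01, -0.46 and -0.43 at 1.2, 12 and 24 mg/kg. The other, an unnamed expressed sequence tag, was -0.77 (SE 0.12). The dose trend passed for these 2 probes (limma adjusted p = 0.0382, 1006 at unadjusted p under 0.05), with falls of 0.89 for Junb and 0.65 for the tag from 0 to 47 mg/kg along the slope. Fhl1, a LIM domain protein, was -0.64 (SE 0.11) and did not pass.

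At 47 mg/kg and 90 days 5 gene lists were lower. The synaptic vesicle list had a median of -0.28 (6 of 23 members higher, camera adjusted p = 0.00845), neuronal structure markers -0.20 (5 of 21, adjusted p = 0.00883), heat shock and protein folding -0.19 (3 of 18, adjusted p = 0.00936), immediate early genes -0.18 (6 of 24, adjusted p = 0.0148) and calcium signalling -0.10 (7 of 26, adjusted p = 0.0339). With an estimated correlation the adjusted p was 0.858 for each. Adjusted over the list alone, 4, 4, 2, 7 and 8 members passed, and over all probes Junb alone. Examples were Syn1 (-0.58, SE 0.14), Ncam1 (-0.59, SE 0.13), Thy1 (-0.93, SE 0.27), Hsp90b1 (-0.73, SE 0.17), Nr4a1 (-0.80, SE 0.22) and Ppp3cb (-0.64, SE 0.15). Of the members passing in their list alone, Fosl2 (0.38, SE 0.13) and Fosl1 (0.28, SE 0.10) of the immediate early genes and Plcg1 (0.31, SE 0.11) of calcium signalling were higher.

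The 2 probes at 47 mg/kg and 90 days were lost (0 in limma) without either of control replicates 1 and 2 or of 47 mg/kg replicates 1 and 2, in 1 fit over 90 animals, with median centring, without background correction, with print-tip loess, with the replicate block, from separate channels, from the submitters' values and without the 2 widest arrays, whose agreement with the rest of their loop was the lowest of 176 (r = -0.434 and -0.26). Array weights gave 1 probe, and 5 and 54 probes passed without control replicate 3 and 47 mg/kg replicate 3. The trend count was 0 without control replicates 1 or 2, 1.2 mg/kg replicates 1 or 3, 12 or 24 mg/kg replicate 3 or any 1 of the 47 mg/kg animals, 1 without 12 mg/kg replicate 1 or 24 mg/kg replicate 2, and 4 without 24 mg/kg replicate 1. At the other doses of 90 days 0 probes passed in limma (295, 412 and 449 at 1.2, 12 and 24 mg/kg at unadjusted p under 0.05). At 12 mg/kg the immediate early list was lower (median -0.15, camera adjusted p = 0.0148) and the ribosomal protein list higher (0.14, 10 of 11 members, adjusted p = 0.0339), as was oxidative phosphorylation (0.09, 13 of 14, adjusted p = 0.0438), with an adjusted p of 0.858 under an estimated correlation.

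The 47 mg/kg effect differed between the 6 times for 22 of 7597 probes (limma F-test, 1086 at unadjusted p under 0.05). Of 100 regroupings of the animals within times, the real one included, 29 reached this count. At 24 hr 19 of them were higher and 3 lower. At 48 hr 11 had less than 0.5 of their 24 hr size, at 7 and 14 days all 22 had, and at 90 days 21 lay on the other side of control. Some of the 21 were within their SE of control, among them Npy (-0.08, SE 0.13) and Narp (-0.14, SE 0.17). Over all probes 31.6% had the same direction at 90 days as at 24 hr. The 22 were picked for effects that differ between times, so these counts are no separate evidence for a time course. Gfap was 1.19 higher at 24 hr and 1.75 at 48 hr, against 0.07, 0.12, -0.07 and -0.19 at the later times (adjusted p = 0.0286, n = 3 per group). Hspb1 was 1.81 and 1.56 higher and Npy 1.31 and 0.98, against -0.11 and 0.04 at 7 days (adjusted p = 0.0314 each, limma). At 28 days Npy was 0.37 (SE 0.20). C1qb was 0.47 and 0.80 higher at 24 and 48 hr, and Vtn, the plasma and matrix protein vitronectin, was -0.67 and -0.60. Pdia3, Cck and Ppp3cb were 1.02, 1.09 and 0.65 at 24 hr and -0.50, -0.71 and -0.64 at 90 days. The smallest adjusted p belonged to Tclone15 (0.00103) and Narp (0.00163, 1.23 higher at 24 hr and 0.70 at 48 hr).

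The count of probes differing between times depended on single animals and on the processing. Among the 24 hr animals it was 1 without 47 mg/kg replicate 2, 2, 265 and 4 without control replicates 1, 2 and 3, and 10 and 65 without 47 mg/kg replicates 1 and 3. Among the 48 hr animals it was 48 and 43 without control replicates 1 and 2, and 78, 12 and 4 without 47 mg/kg replicates 1, 2 and 3. It was 71 without 7 day control replicate 2, and 184, 168 and 167 without 28 day control replicate 3 and 47 mg/kg replicates 1 and 3. Among the 90 day animals it was 3, 5 and 104 without control replicates 1, 2 and 3, and 3, 3 and 72 without 47 mg/kg replicates 1, 2 and 3. It was 2 from separate channels and from the submitters' values, and 253 without background correction.

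**Figure D2:**
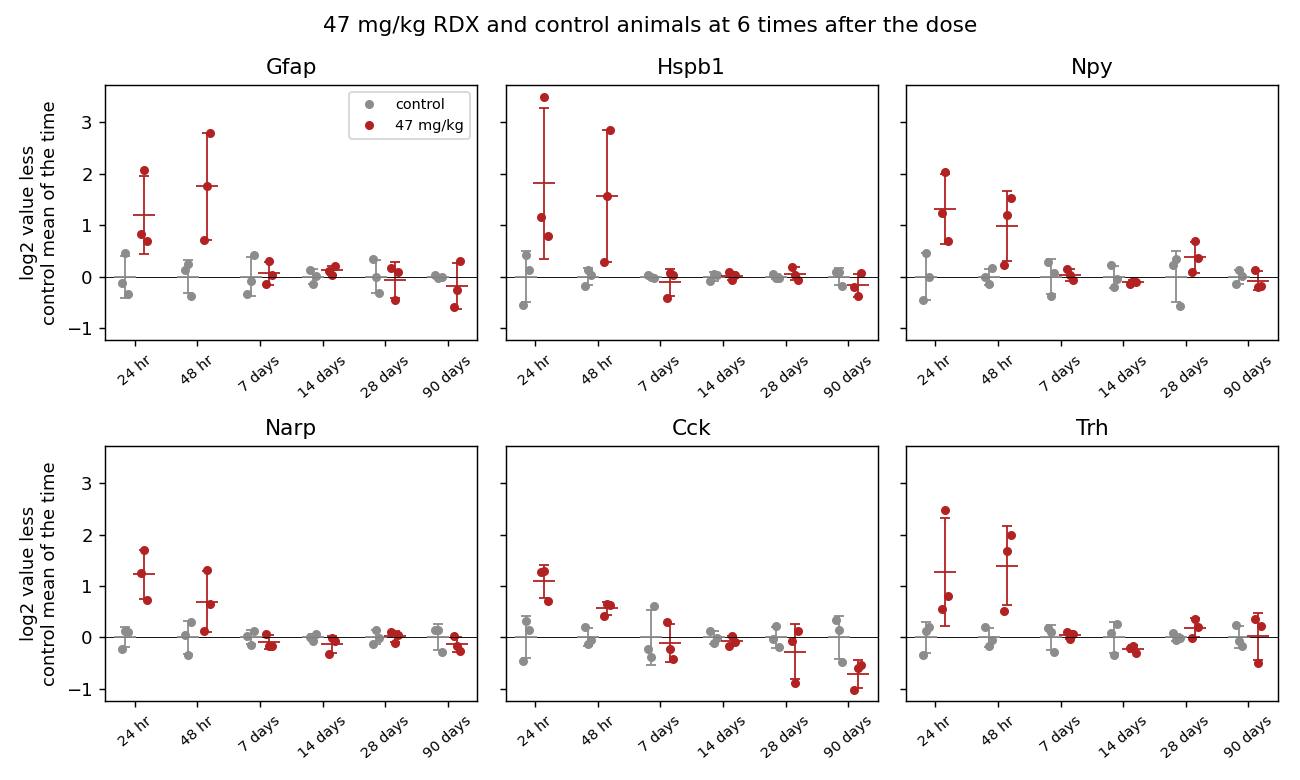
Log2 value relative to the control mean of the same time (vertical axis) at 6 times after dosing (horizontal axis) for Gfap, Hspb1, Npy, Narp, Cck and Trh, in control and 47 mg/kg animals, with 1 point per animal and mean and SD of 3 animals. The 47 mg/kg mean of Gfap lies 1.19 and 1.75 above control at 24 and 48 hr and within 0.19 of it later.

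Of 600 list tests over all doses and times, 30 passed camera with the preset correlation, 20 of them up. With an estimated correlation 0 passed (smallest adjusted p = 0.858), and fry gave 1 for a shift in 1 direction and 11 for changes in either direction. Among markers of other cell types, myelin genes (median 0.00 at 24 hr, -0.01 at 48 hr), blood and endothelial markers (-0.01 and 0.22) and pituitary hormone genes (-0.10 and 0.06) did not pass at 47 mg/kg. Inflammatory signalling genes had medians of -0.02 and 0.06, GABA genes of -0.00 and 0.07 and glutamate receptor and transport genes of -0.02 and 0.02 at these times, none passing.

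**Figure D3:**
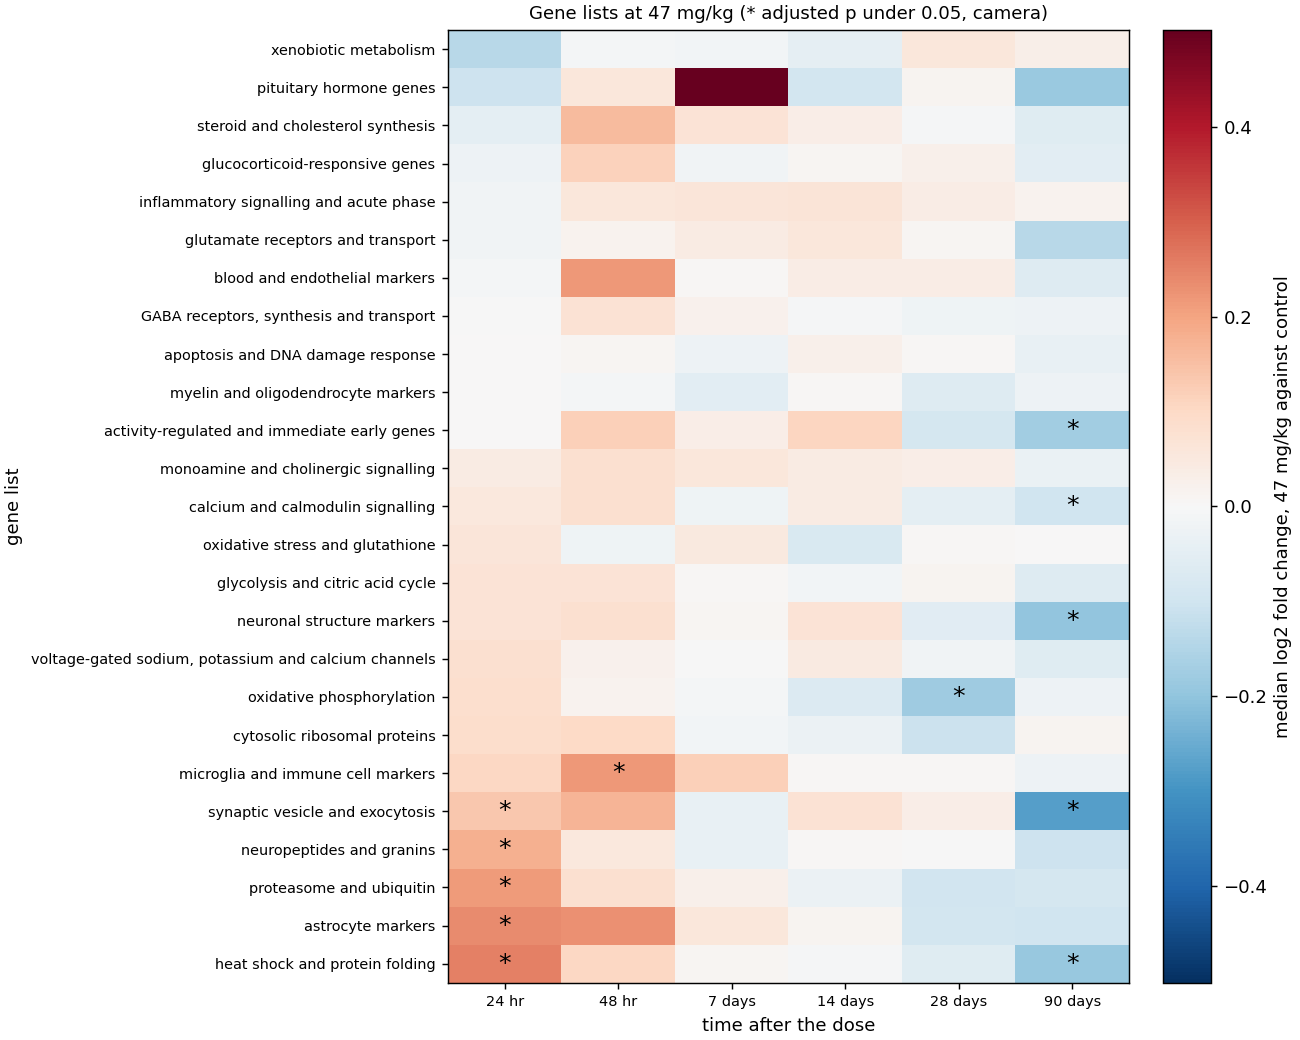
Median log2 difference between 47 mg/kg and control (colour) of 25 gene lists (vertical axis) at 6 times (horizontal axis), where a star marks camera adjusted p under 0.05 with the preset correlation. The 5 starred lists at 24 hr have medians from 0.14 to 0.25, and the 5 at 90 days from -0.28 to -0.10.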

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

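The own-channel signal tests of the 24 hr trend, the 4 tests of the 90 day lists, both tests of the left-out array and the prediction for single doses were chosen after the results were seen. The other tests were written down before.

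A test of the difference between times (limma F-test over 90 animals, n = 3 per group) singled out 22 probes whose 47 mg/kg effect was not the same at all 6 times. Those with a gene symbol were Gfap (adjusted p = 0.0286), Pdia3 (0.0299), C1qb, Vtn, Cck, Npy and Hspb1 (0.0314 each), and Gdi2, Ppp3cb and Pitpna (0.0391 each). In Gfap, Npy, Hspb1 and C1qb the 47 mg/kg values were high at 24 and 48 hr and nearer to control later, with Npy still 0.37 higher (SE 0.20) at 28 days. In Gdi2 and Pitpna they were 0.84 and 0.59 at 24 hr against -0.49 and -0.25 at 90 days.

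The 47 mg/kg effects that differed between times (22 probes) were set against 7 day arrays with little signal over background and against the array left out for unsettled dyes. Without the 7 day data, 22 of the 22 probes passed (100 in all), which argues against the 7 day arrays as the cause. With the array added, the median ratio of the 24 hr effect to the reported one was 0.94 with its 47 mg/kg animal read as Cy3 (quartiles 0.883 and 0.98, 7 probes passing in limma) and 0.763 with it read as the other dye (quartiles 0.733 and 0.815, 1 probe passing), which argues against its absence making the whole effect, although most calls depended on it. When control and 47 mg/kg animals were regrouped within times, 29 of 100 groupings gave at least 22 probes, the highest of the others giving 489, so chance is not excluded for the count, and the large counts of other groupings point to a structure among the animals that was not identified. Slide batches and recovery with time stay open: 24 and 48 hr, with slide codes nearly alike, differed in 0 of 7597 probes (limma, 423 at unadjusted p under 0.05), and the later times had other batches.

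The dose trend at 24 hr (392 probes) was set against falling array signal, a brightness trend and the control animals alone. With each animal's mean array signal in the fit the median slope ratio was 1.02 (quartiles 0.971 and 1.05, 228 probes passing), with its own channel's signal over background 0.993 (333 passing), and after removing a loess on brightness 380 probes passed, 335 of them shared. The net signal of the animal's own channel fell with dose (r = -0.518, permutation p = 0.0475, rho = -0.578, permutation p = 0.0277, adjusted p = 0.285 over 6 times, r = -0.528 to -0.378 without 2 of the 3 controls, whose dose was farthest from the median, and -0.341 without all 3), and with it in the fit the median slope ratio was 0.985 but 0 probes passed in limma: the median slope went from 0.0903 to 0.0916 and its SE from 0.0227 to 0.0271, so the calls ended because the error grew, not because the slopes shrank. Over the 12 dosed animals alone the slope was 0.86 of that over 15, reached by 3 of 100 orders of the doses, the real one included. The other orders had a median of 0.662 (highest 0.892), so only the excess over it bears on the order of the doses. This argues against the controls alone, although 0 probes passed there (909 at unadjusted p under 0.05). A dose effect may therefore underlie the trend, as a hypothesis, but separate channels and the submitters' values gave 0 probes and leave array processing open.

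The lists that were lower at 47 mg/kg and 90 days (112 members of 5 lists) were set against the 2 widest arrays, exchanged labels on them, 47 mg/kg replicate 1 (on 1 of them) and control replicate 2 (on both). Without both arrays the members' median went from -0.175 to -0.126, a ratio of 0.72, with Junb at -0.88 (SE 0.16, limma adjusted p = 0.164, n = 3), so they account for part of the shift and not the whole. Of the 12 lists called at 47 mg/kg over all times, 2 lost their camera call without these arrays. Without replicate 1 the ratio was 0.987 and without control replicate 2 it was 1 (Junb -0.84 and -0.91, limma adjusted p = 0.21 and 0.402). This argues against the value of either animal as the whole cause. The arrays of the animal left out stayed in the loop fit, so it cannot show what they added to the values of other animals. The 2 arrays agreed least with their loop (r = -0.434 and -0.26, the lowest of 176), and with their labels exchanged the median was -0.0189, a ratio of 0.108, with Junb at -0.39 (SE 0.23, limma adjusted p = 0.999), so exchanged labels may underlie part of the shift, although the other arrays alone kept 0.72 of it. A late effect of dose and correlation between list members stay open as well, since no list passed with an estimated correlation (adjusted p = 0.858).

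Other groupings of the animals were tried for each count. The 6 animals of 1 dose and the control make 10 splits, too few for a share under 0.05. In 22 of the 24 comparisons the real count was 0, which all 10 splits reached. Among these the highest of the other splits gave 13 probes for 12 mg/kg at 7 days, 2 for 1.2 mg/kg at 28 days and 26 for 47 mg/kg at 28 days, and 0 in the rest. At 48 hr and 12 mg/kg 1 split gave as many as the real 1 probe (highest other 0). At 90 days and 47 mg/kg 2 splits gave at least the real 2 probes, and the highest other gave 237, with control replicates 1 and 2 and 47 mg/kg replicate 3 on 1 side, which points to a structure of the samples other than dose. For the dose trend at 24 hr 1 of 100 orders of the doses, the real one, reached 392 probes (highest other 0). This argues against a random order of the doses giving that count. Animals of neighbouring doses shared arrays, and reordering breaks this, so the test cannot exclude array error along the dose order. At 90 days the real order alone reached 2 probes (1 of 100, highest other 0). At other times reordered doses gave up to 33 probes, so chance is not excluded for a count of 2. For the trends at 48 hr, 7, 14 and 28 days the real count was 0, reached by 100 of 100, and the highest others were 33, 1, 1 and 16. Of 100 regroupings, the real one included, 2 called as many lists at 47 mg/kg as the real 12 (highest other 12). Chance thus rarely gave this number, but another regrouping matched it, so chance is not excluded. Nor is it for any 1 list, since 69 of the other regroupings called at least 1.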

How the results depend on the processing

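Array weights, print-tip loess, both readings of the left-out array, the 90 day data without the 2 widest arrays, the stricter filter, the 14 day data without the array of another slide batch (0 probes at each dose, 309, 521, 447 and 475 at unadjusted p under 0.05) and the centred submitters' values were chosen after seeing the data; the other alternatives were not. Of 1498 values of called dose slopes under alternatives, 934 kept their direction and their side of the threshold, 555 kept the direction alone and 9 turned. Of 59 values of called fold changes 21 kept both and 38 the direction alone, and of 1133 adjusted p of probes differing between times 782 stayed under 0.05. Of 660 values of called lists at 47 mg/kg 597 kept their call. Of the 660, 432 came from leaving out 1 animal, which refitted the time of that animal alone. Lists of other times could then change only through the adjustment, so the 597 overstate how stable the calls were. Of 217 values of lists with a dose trend 34 lost their call. These 34 included all 7 trend lists with the centred submitters' values, 5 of 7 from separate channels and 3 of 7 from the submitters' values. Of 3753 values of named genes that did not pass, 3084 stayed close, 594 moved by more than the SE of the main value and 75 passed. Signal over background limited the 7 day data most (1.33 in Cy3), and the stricter filter kept 2005 probes there. Where no cause is given below, the cause was not tested. Counts are limma's.

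The dose trend at 24 hr (392 probes) stayed between 363 and 568 with no background correction, print-tip loess, median centring, no dye term, the replicate block (465), no filter, the stricter filter and without repeat arrays. It was 741 in 1 fit over 90 animals, 225 with array weights, 213 with dose as its rank, 165 with the left-out array added in Cy3 and 3 with it added in the other dye, and 0 from separate channels, 0 from the submitters' values and 0 from these values centred (622, 855 and 553 at unadjusted p under 0.05).

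In 1 fit over 90 animals, which pools the spread over times, the counts were 45, 101 and 167 at 12, 24 and 47 mg/kg at 24 hr, 3, 161, 96 and 11 at 1.2, 12, 24 and 47 mg/kg at 48 hr, 3 and 8 at 12 and 24 mg/kg at 7 days, 9 at 24 mg/kg at 28 days and 0 at 47 mg/kg at 90 days. The trend counts were 107 at 48 hr, 14 at 7 days, 297 at 28 days and 0 at 90 days.

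The 1 probe at 12 mg/kg and 48 hr became 0 with no background correction, no dye term, print-tip loess, separate channels, the submitters' values and these centred (1116, 981, 1198, 450, 1352 and 422 at unadjusted p under 0.05, in this order), and 36 with the replicate block, which also gave 13 at 24 mg/kg. The replicate numbers showed no clear pairing of the animals, and the cause was not tested.

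The 2 probes at 47 mg/kg and 90 days became 0 with median centring, no background correction, print-tip loess, the replicate block, separate channels, the submitters' values, these centred, and without the 2 widest arrays (1052, 1140, 1187, 1172, 127, 223, 160 and 773 at unadjusted p under 0.05, in this order), and 1 with array weights. Their trend became 0 with median centring, print-tip loess, the replicate block, separate channels, the submitters' values, these centred, and without the 2 widest arrays (915, 1056, 1011, 288, 404, 290 and 605 at unadjusted p under 0.05), 1 with no background correction and 4 with array weights.

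At other times, no background correction gave a trend for 1 probe at 48 hr and 4 at 14 days, print-tip loess 1 probe at 24 mg/kg and 14 days, and leaving out repeat arrays 1 at 24 mg/kg, 1 at 47 mg/kg and 2 in the trend at 7 days. The submitters' values gave 1 probe at 12 mg/kg and 7 days (also 1 when centred), and 1452 and 874 at 12 and 24 mg/kg and 14 days. The last 2 were lost by centring each sample, which shows that they came from the samples' medians.

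The 22 probes differing between times became 253 with no background correction, 147 with the stricter filter, 69 with the replicate block, 66 with print-tip loess, 64 without repeat arrays, 12 with array weights, 7 and 1 with the left-out array in Cy3 and in the other dye, 4 without the 2 widest arrays, and 2 from separate channels, 2 from the submitters' values and 2 from these centred. The 12 lists called at 47 mg/kg became 23 with median centring, 6 from separate channels, 0 with an estimated correlation and 0 with fry.

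The 9 slopes that turned were, from separate channels, Glud1 (-0.0297); from the submitters' values, Mdh2 (-0.00588), Glud1 (-0.0517) and the 90 day sequence tag (0.0195); and from these centred, Glud1 (-0.0254), Htr1d (0.00886), a probe described as FZ6-like protein (0.00116), the second Cyp2c12 probe (0.0105) and the 90 day tag (0.0312).

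Leaving out each animal in turn left 2 animals in a group, which share the spread of the others. The arrays of the animal left out stayed in the loop fit that gave the animal values. At 24 hr the counts ranged from 0 to 1, 0 to 107, 0 to 370 and 0 to 380 at 1.2, 12, 24 and 47 mg/kg, the highest without control replicate 3 at 1.2 mg/kg and control replicate 2 at the others, and from 2 to 697 in the trend. At 48 hr they ranged from 0 to 1, 0 to 2, 0 to 2 and 0 to 7. At 14 days they ranged from 0 to 1 at 1.2 and 12 mg/kg and in the trend, and at 28 days from 0 to 1 at 24 mg/kg and in the trend. At 90 days they ranged from 0 to 54 at 47 mg/kg and from 0 to 4 in the trend. Probes differing between times ranged from 1 to 265 and called lists at 47 mg/kg from 10 to 15. The other counts stayed at 0 to 0.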

Other observations

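The tests of pairs of times compare their 47 mg/kg fold changes and were written down before their results were seen, as were the list tests, while the count of probes with the same direction was chosen after. Correlations are across 7597 probes, which are not independent replicates, and each was set against 100 pairs of splits of the control and 47 mg/kg animals, the real one included.

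At 48 hr and 47 mg/kg the blood and endothelial markers had a median of 0.22 and the steroid and cholesterol synthesis genes of 0.16, neither list passing camera. At 1.2 mg/kg and 28 days the myelin list was lower (median -0.15, 3 of 14 members higher, camera adjusted p = 0.0358) and the immediate early list higher (0.11, 19 of 24, adjusted p = 0.0468), while at 12 mg/kg and 90 days the oxidative stress list was higher (0.09, 15 of 20, adjusted p = 0.0358), each with an adjusted p of 0.858 under an estimated correlation. Choroid plexus markers were too few (4) to test. Among genes with several probes, Add1, a membrane skeleton protein, had 24 hr slopes of 0.107 and -0.048, and Csnk2b of 0.112 and 0.00187.

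A 47 mg/kg effect shared by 24 and 48 hr was a hypothesis, and the fold changes correlated with r = 0.478, a size reached by 2 of 100 pairs of splits (adjusted p = 0.1 over 15 pairs of times, the permutation p being adjusted by Benjamini-Hochberg). The 24 hr and 90 day fold changes were opposed, with r = -0.563 (1 of 100, adjusted p = 0.075, permutation), as were 48 hr and 90 days (r = -0.375, 3 of 100, adjusted p = 0.112, permutation) and 14 and 90 days (r = -0.224, 1 of 100, adjusted p = 0.075, permutation). None of these passed after adjustment. The other pairs gave r = -0.0514 (24 hr and 7 days, 72 of 100), 0.16 (24 hr and 14 days, 9), -0.279 (24 hr and 28 days, 24), -0.0302 (48 hr and 7 days, 87), 0.2 (48 hr and 14 days, 5), -0.227 (48 hr and 28 days, 25), -0.0196 (7 and 14 days, 69), 0.0112 (7 and 28 days, 94), 0.0184 (7 and 90 days, 86), -0.0134 (14 and 28 days, 92) and 0.296 (28 and 90 days, 20).

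Of the 100 probes with the smallest p at 24 hr and 47 mg/kg, 97 had the same direction at 48 hr, 45 at 7 days, 77 at 14 days, 21 at 28 days and 1 at 90 days. Over all probes these shares were 64.5%, 48.7%, 54.9%, 39.4% and 31.6%. A candidate explanation for the opposed 90 day values is a rebound of early genes such as Cck, Pdia3 and Ppp3cb, but a shared axis of sample or array quality with opposite sign at both times would give the same r = -0.563, and no test here separates them.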
